A study of Mus musculus with 5 samples.

How the data were processed

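RNA came from the dLGN of mice on a C57BL/6 background, dissected from vibratome sections of 200 µm at postnatal day 0. Per the labels' protocols, 20 ng of total RNA was amplified with a Nugen Ovation kit, biotin-labelled and hybridised to Affymetrix arrays. The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes. RMA subtracts background, normalises quantiles between arrays and summarises the probes of a set. Its version and settings are not given in the sources used here. The log2 scale was read from the range of the deposited values. RMA pulls the distributions of arrays together, so a change shared by most genes would not be seen, and it compresses differences near the background.

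The groups were taken from the genotype labels, 2 arrays for the knockout and 3 for the heterozygous control. Of 45101 probe sets, 64 control probe sets of the array were left out of the tests, which left 45037. The platform annotation gave 34945 of these 1 gene, 932 several genes and 9160 no gene. Symbols were looked up by gene ID in the RefSeq gene table of GRCm38.p6, where 34741 probe sets were found and 0 symbols changed. No gene was named from a probe set with several genes. The array medians lay between 6.39 and 6.42, and correlations across probe sets between pairs of arrays lay between 0.985 and 0.995, so no array was a copy of another. Between 745 and 1172 probe sets held exactly equal values in a given pair of arrays, with 867 in the knockout pair.

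The knockout was compared with the control with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with the genotype as the only term and Benjamini-Hochberg adjustment over all 45037 probe sets. The prior had 2.52 degrees of freedom beside 3 residual ones. Every adjusted p of a gene comes from this fit unless it is said to be adjusted over a list alone. For gene lists, each gene was represented by the probe set with the highest mean over the 5 arrays, which gave 18193 genes. There were 29 lists of pathways, cell type markers, RNA quality genes, sex-linked genes and neighbours of Sema6a, tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list moves on balance one way without comparing it with other genes, were run beside it. Of the camera calls at the preset correlation, 0 held with an estimated one, and fry kept the microglia list (adjusted p = 0.00234). The signs of the median, the mean and the camera test were not all alike for the lists of semaphorin effectors, relay neurons, nuclei-patterned genes, habenula, activity-regulated genes, axon growth, oxidative phosphorylation, sex-linked genes and Sema6a neighbours. Intervals of list medians are 95% bootstrap intervals over members from 10000 draws and do not cover the spread between pools.

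The test, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule, applied to the brightest probe set of each gene, named Sema6a first. It then took, in each direction, up to 12 genes with the largest change among those past an adjusted p of 0.05, filled up by the smallest unadjusted p. Such genes had to reach the median level of 6.39 in 1 group and have every knockout array on one side of every control array. Gene models without an assigned symbol were passed over. From each list up to 4 members with the smallest p above the same level were named, and further members in the text were chosen after their values were seen.

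The fit was tested on 20 simulated data sets of 45037 probe sets, with the variances of this comparison and 200 probe sets changed. It recovered 44.4% of those changed 2-fold and 95.2% of those changed 4-fold, with 8.25 false calls per data set on average. Both simulated groups had the same variances. The SD of the difference between arrays was 0.463 for the knockout pair and 0.303 to 0.337 for control pairs. In the data themselves, Sema6a probe sets that differed 4.81-fold and 5.75-fold missed the adjusted threshold. The recovered shares therefore do not give the share of such changes found in these data. Camera found a list of 20 genes shifted by 0.5 in 100% of the data sets and called an unshifted one in 5%. The simulated probe sets varied independently of each other, whereas the GABAergic list had an estimated correlation of 0.706. The 5% therefore does not give the rate of false list calls in these data.

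The alternatives were the replicate number as a block, a further quantile normalisation, centring of each array, leaving out dim probe sets, an intensity trend or a robust prior in eBayes, array weights, each array left out in turn, a looser threshold, a minimum fold of 1.5 and the mean of all probe sets of a gene.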

Results

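Gene expression was measured in the dorsal lateral geniculate nucleus (dLGN), the thalamic relay of the visual pathway, of newborn mice at postnatal day 0. The comparison set mice lacking both copies of Sema6a, which encodes a transmembrane semaphorin that acts in axon guidance, against heterozygous controls of the same age that carried 1 working copy. There were 5 arrays, 2 from knockout pools and 3 from control pools. Per the series description, each pool combined nuclei of pups of 1 genotype taken from more than 1 litter. The limma p-values of genes therefore measure the spread between pools. Camera at a preset correlation compares the genes of a list with other genes, so its p-values do not. The number of arrays limits the precision, and with 2 pools against 3 an exact permutation test of a single value could not give a p below 0.1.

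Sema6a itself was lower in both knockout pools than in every control pool. Its brightest probe set read 7.83 ± 0.03 on the log2 scale in the knockout (SD, n = 2) and 10.50 ± 0.13 in the control (SD, n = 3). The log2 fold change was -2.68 with a standard error of 0.12, a 6.39-fold difference (limma adjusted p = 0.0236). The other probe sets of the gene gave -2.27 and -2.52, each with an adjusted p of 0.0546. The knockout level of the brightest probe set stayed above the median of all probe sets, 6.39. The labels do not say which part of the gene was disrupted, so signal left at a probe set does not measure functional transcript. In the GRCm38.p6 annotation Sema6a lies on chromosome 18 from 47245254 to 47371200.

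The question of the comparison was which other transcripts differ in the newborn dLGN when Sema6a is lost. Genes of microglia, the resident macrophages of the brain, were among those that rose in the knockout, and the neuropeptide gene Cck fell. In all, 33 of 45037 probe sets passed an adjusted p of 0.05 in limma, 29 higher and 4 lower in the knockout. They named 26 distinct genes, 22 higher and 4 lower, while 3 of the probe sets matched several genes and 2 had no gene name. At an unadjusted p under 0.01 there were 828 probe sets higher and 731 lower, against 450 expected in total with no difference. Every knockout array lay on one side of every control array for 27.3% of probe sets, where chance gives 20%. With any 1 of the 5 arrays left out, 0 probe sets passed the adjusted threshold in limma, and between 3694 and 8397 had an unadjusted p under 0.05 against 2252 expected.

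Among the named genes that rose, 6 are known from myeloid cells. Lyz2, the lysozyme of macrophages, rose by 2.98 on the log2 scale, from 5.86 ± 0.19 in the control (SD, n = 3) to 8.85 ± 0.01 in the knockout (SD, n = 2). Tyrobp, the signalling adaptor of microglial surface receptors, rose by 2.46 and Ly86, a partner of a Toll-like receptor homologue, by 2.42. Fcgr3, a receptor for immunoglobulin G, rose by 2.08. P2ry6, a nucleotide receptor of microglia, rose by 1.86, and Cebpa, a transcription factor of the myeloid lineage, by 1.65. The adjusted p-values of these 6 genes in limma lay between 0.0236 and 0.0360.

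The other named genes that rose include genes of neurons. Gpr39, a zinc-sensing receptor, rose by 2.99, with 9.65 ± 0.14 in the knockout (SD, n = 2) and 6.67 ± 0.26 in the control (SD, n = 3). Lypd1, a modulator of nicotinic acetylcholine receptors, rose by 2.77, and its other probe set gave 3.20 (limma adjusted p = 0.115). The annotated spans of Gpr39 (125676996 to 125873862) and Lypd1 (125867622 to 125913175) overlap on chromosome 1. Whether each probe set reads only its own gene was not tested, so these rises may not be separate. Pcdh17, a protocadherin of the cell surface, rose by 2.24 and by 2.18 at its other probe set. The first of these held the same value, 10.99, in both knockout arrays, which narrows its spread, and the other probe set gave an adjusted p of 0.0236. Kif26b, of the kinesin family, rose by 2.19, Evi2a by 2.17 and Nrgn, a calmodulin-binding protein of dendrites, by 1.88. A second probe set of Evi2a differed by 0.04, and its level of 2.60 in the knockout was far below the array median. The adjusted p-values of these 6 genes in limma lay between 0.0236 and 0.0395. With array weights Lypd1 (adjusted p = 0.0608), Pcdh17 (0.0573), Evi2a (0.0608) and the myeloid gene Fcgr3 (0.0521) lost their calls.

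Of the 2 named genes that fell besides Sema6a, Gsg1l, an auxiliary subunit of AMPA-type glutamate receptors, fell by 2.51 on the log2 scale (limma adjusted p = 0.0331). Cck, which encodes cholecystokinin, fell by 2.12, from 11.87 ± 0.05 in the control (SD, n = 3) to 9.75 ± 0.06 in the knockout (SD, n = 2; limma adjusted p = 0.0236). The 11 other genes past the threshold, which the naming rule at the brightest probe set of each gene did not take, were chosen after their values were seen. Of these, Slc7a14, AW551984, Rspo2, Sdk1, C3ar1, Pld4, Pcdh11x, Ssbp2, C1qb and Cd86 rose and Osbpl3 fell. The next named genes on the lower side missed the adjusted threshold. They were Muc15 at -1.66, Rprml at -1.08, the potassium channel gene Kcnn1 at -1.60, Snx31 at -2.36, S100a8 at -2.46, Sox13 at -0.98, the Wnt inhibitor gene Dkk4 at -1.995, Ptpn22 at -2.40, Ak5 at -0.93 and Egflam at -1.53, with adjusted p-values from 0.0546 to 0.0834.

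**Figure D1:**
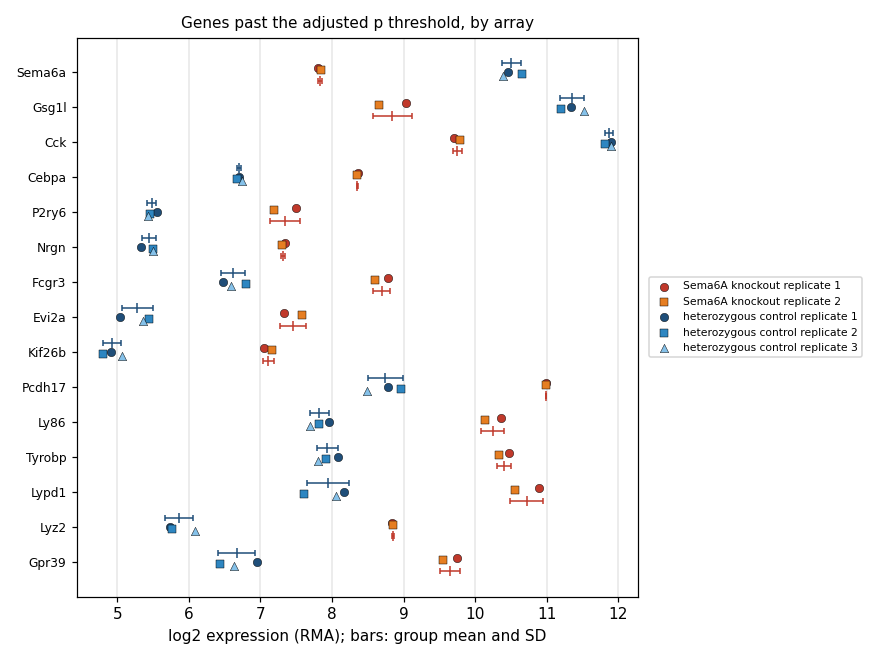
Expression of Sema6a and of the 14 named genes that passed the adjusted threshold. The x axis gives log2 RMA values, each symbol is 1 array, and the bars give the mean and SD of the 2 knockout pools (red) and the 3 control pools (blue). Sema6a lies near 7.83 in the knockout and 10.50 in the control, and for each gene the arrays of the 2 groups do not overlap.

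Microglia and macrophage markers rose as a group. Of 18 measured members, 17 had higher means in the knockout, with a median log2 fold change of 1.51 (95% bootstrap interval over members 1.12 to 2.03). The camera test at the preset correlation gave an adjusted p of 1.03e-20 over 29 lists. With an estimated correlation the camera adjusted p was 0.0537, so this call was lost there. The estimated correlation was -0.00089, under the preset 0.01, so correlation between members does not account for the loss. The value of 1.03e-20 rests on genes as units and does not measure the spread between pools. Adjusted over all genes, Lyz2 and Tyrobp rose, as did C1qb at a probe set other than its brightest, and adjusted over the list alone 16 members rose and 0 fell. Cx3cr1, the fractalkine receptor of microglia, rose by 1.85 and Fcer1g, an Fc receptor subunit, by 1.95 on the latter basis. Tmem119 and P2ry12, genes of resident microglia, rose by 1.10 and 1.38. Itgam, at 0.23, and Mrc1, a gene of macrophages at brain borders, at -0.54, did not pass. The median of the list lay 1.64 above the control mean in knockout replicate 1 and 1.56 above it in replicate 2.

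**Figure D2:**
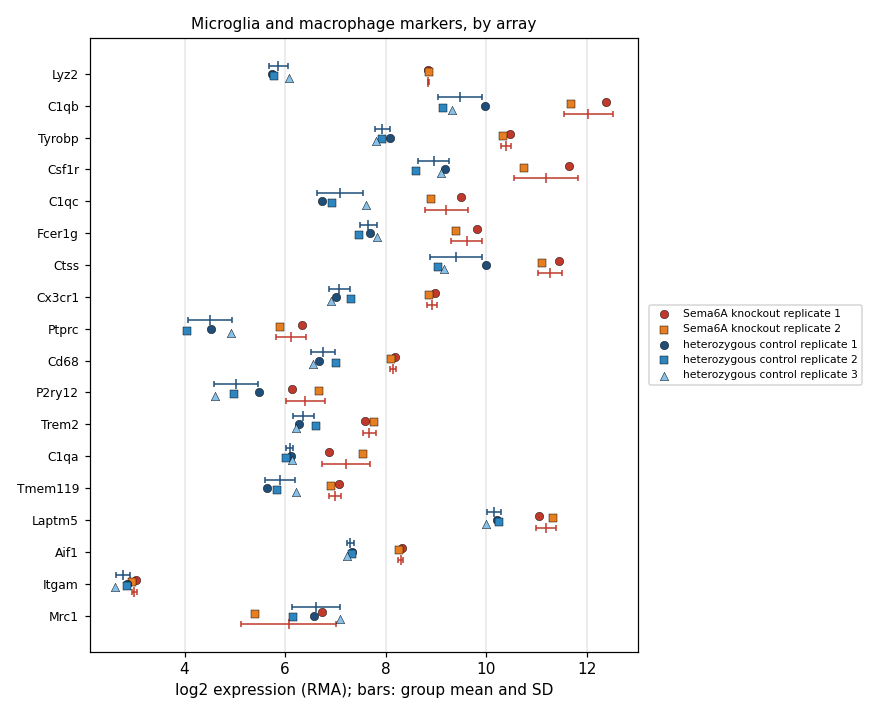
The 18 measured microglia and macrophage markers. The x axis gives log2 RMA values, each symbol is 1 array, and the bars give the mean and SD of the 2 knockout pools (red) and the 3 control pools (blue). For the 16 members that rose, both knockout arrays lie to the right of the controls, whereas for Mrc1 the groups overlap.

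GABAergic and prethalamic markers were higher mainly in knockout replicate 1. For 9 of 23 members both knockout arrays lay above every control. All 23 measured members had a positive log2 fold change, with a median of 1.06 (95% bootstrap interval 0.24 to 1.28) and a camera adjusted p of 0.000289, but the adjusted p = 0.974 with an estimated correlation. Adjusted over the list alone, and over all genes, 0 members passed in limma (4 had an unadjusted p under 0.05), and the list's median lay 2.39 above the control mean in knockout replicate 1 and 0.09 above it in replicate 2. Isl1, a transcription factor of the ventral lateral geniculate nucleus and prethalamus, read 9.12 in knockout replicate 1 and 4.59 in replicate 2, against 2.87 to 3.94 in the controls. Dlx2, a transcription factor of GABAergic precursors, read 8.18 and 4.33. The neuropeptide genes Npy (2.42) and Sst (2.06) and Gata2 (0.43) followed the list with adjusted p-values over the list of 0.259. Without knockout replicate 1 the mean of the list was 0.07 and the camera adjusted p was 0.677. In that array the 3′ control probe set of Gapdh exceeded the 5′ one by 2.34, against 0.77 to 1.33 in the controls.

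Lists of markers of other cells were not called with all 5 arrays. Over the erythroid genes the median log2 fold change was -0.10, and the globin gene Hba-a2 gave -0.29. Slc4a1, the anion exchanger of red cells, was the 1 erythroid gene that fell adjusted over the list alone (-0.82), with 0 past the threshold over all genes. The median was -0.25 over meningeal and fibroblast markers, where Col1a1 gave -1.95, 0.05 over choroid plexus and ependymal markers, 0.13 over endothelial and pericyte markers, and 0.09 over radial glia and astrocyte markers. These 4 lists had 0 members past the threshold adjusted over the list alone in limma. At an unadjusted p under 0.05, 4 endothelial genes were higher, 1 astrocyte gene was lower, and 1 meningeal gene went each way. Camera adjusted p-values for these 5 lists lay between 0.280 and 0.766. The endothelial list passed without knockout replicate 1 (mean 0.25, adjusted p = 0.0310) and without control replicate 2 (0.25, adjusted p = 0.00944), both at the preset correlation. With all arrays it gave an adjusted p = 0.974 with an estimated correlation. The mean of the meningeal list went from -0.24 to 0.03 without control replicate 3.

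Oligodendrocyte lineage markers gave a median of 0.21 over 15 members, with a camera adjusted p of 0.0529 (adjusted p = 0.974 with an estimated correlation). Adjusted over the list alone 4 rose and 2 fell, against 0 over all genes. Mbp, a myelin protein gene, rose by 1.55, Sox10, the lineage's transcription factor, by 0.83 and Pdgfra, the receptor of its precursors, by 0.42, while Mag, a myelin adhesion gene, fell by 0.92. The list passed without knockout replicate 1 (mean 0.34, adjusted p = 0.0244) and without control replicate 1 (0.27, adjusted p = 0.0154).

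**Figure D3:**
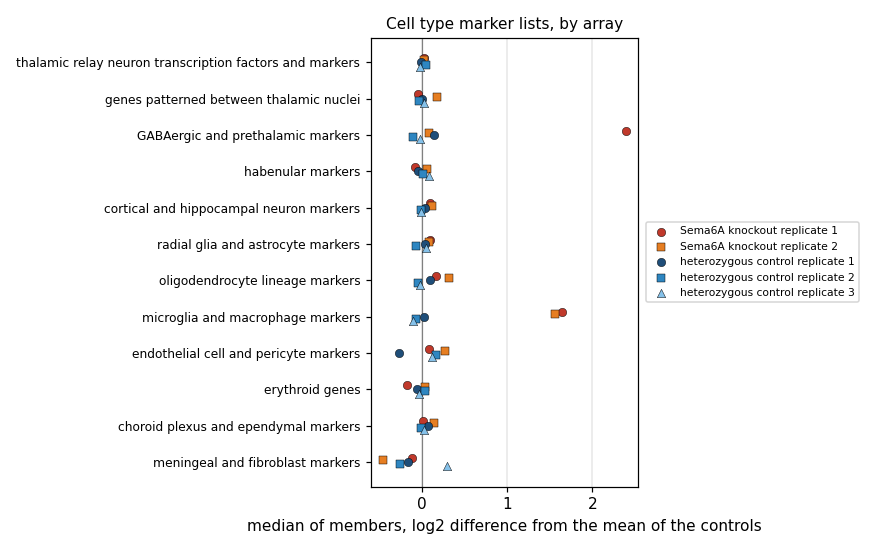
Cell type marker lists by array. Each symbol is the median over a list's members, in 1 array, of the log2 difference from the mean of the 3 controls. The microglia list lies at 1.64 and 1.56 in the 2 knockout arrays, and the GABAergic list lies at 2.39 in knockout replicate 1 and at 0.09 in replicate 2.

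None of the lists of thalamic identity was called. Markers of thalamic relay neurons had a median of 0.04 and a camera adjusted p of 0.989. Adjusted over the list alone, Nr2f2, a nuclear receptor of thalamic and ventral forebrain cells, rose by 0.79 and Slc18a2, the vesicular monoamine transporter that sensory thalamic axons express after birth, fell by 0.87. Genes patterned between thalamic nuclei had a median of 0.00 and a camera adjusted p of 0.930, with 4 members up and 3 down adjusted over the list alone and only Cck past the threshold over all genes. The means of both lists differed in sign between the knockout arrays, at -0.10 in replicate 1 and 0.27 in replicate 2 for relay neurons and at -0.15 and 0.31 for nuclei-patterned genes. The calcium-binding gene Necab1 rose by 0.98, Lrrtm3 by 0.71, and the ephrin receptor gene Epha7 fell by 0.61. The serotonin transporter gene Slc6a4 read 7.98 in knockout replicate 1, against 10.60 in replicate 2 and 10.60 to 10.85 in the controls. Cortical and hippocampal markers had a median of 0.12 (camera adjusted p = 0.612), with Rprm up by 1.11, Bcl11b up by 1.58 and Id2 down by 0.90 adjusted over the list alone and 0 over all genes. Habenular markers had a median of 0.01 and a camera adjusted p of 0.900, with 0 members past either threshold in limma and 2 in each direction at an unadjusted p under 0.05. The mean of the habenular list was -0.11 in knockout replicate 1 and 0.17 in replicate 2.

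Among guidance genes, single members rose or fell, and none of the lists was called. Of 30 semaphorins, plexins and neuropilins, 4 rose and 2 fell adjusted over the list alone, and 0 passed over all genes. Plxna2, which encodes a receptor for Sema6A, rose by 1.45 and Plxnc1, the receptor for Sema7A, by 1.35, while Sema5a fell by 0.95 and Sema7a by 0.87. Of 19 ephrins and Eph receptors, Ephb1 rose by 0.89, Efnb2 by 0.81 and Epha7 fell by 0.61 on the same basis. Of 23 genes of Slit, Robo, netrin and draxin signalling, 5 rose and 0 fell adjusted over the list alone, and 0 passed over all genes. Among the 5 were the netrin receptor gene Dcc (0.98) and the adhesion genes Flrt1 (1.61), Flrt3 (0.88) and Flrt2 (0.59). Of 24 intracellular effectors of semaphorins 0 passed in limma, with Mical2 at -0.93, and at an unadjusted p under 0.05 1 was higher and 3 were lower. The camera adjusted p-values of these 4 lists lay between 0.377 and 0.900.

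Cadherins, protocadherins and contactins included 8 members that rose and 2 that fell adjusted over the list alone, of 35 measured, with Pcdh17 past the threshold over all genes. Pcdh11x passed over all genes at a probe set other than its brightest (1.49, adjusted p = 0.0395). Pcdh8 rose by 1.30, Pcdh11x, at its brightest probe set, by 1.22 and Pcdh18 by 0.90 on the first basis. Cdh7 fell by 0.74. The camera adjusted p of the list was 0.129.

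None of the ion channel and synaptic lists was called, with camera adjusted p-values from 0.297 to 0.658. Of the voltage-gated channel genes, Kcna1 fell by 1.72, and Kcnd2 rose by 0.90 and Kcnc2 by 0.80 adjusted over the list alone. Of the receptors for GABA and glycine, Gabrg1 rose by 1.10 and Glra3 by 1.38, and Gabrg3 fell by 0.65 on that basis. Of the release machinery, the calcium sensor gene Syt2 rose by 0.99. Of 26 ionotropic glutamate receptor genes 0 passed in limma, with Grin3a at 1.21, and at an unadjusted p under 0.05 2 were higher and 3 lower. Over all genes, 0 members of these 4 lists passed in limma.

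The remaining lists gave camera adjusted p-values from 0.297 to 0.989. Of 30 activity-regulated genes 3 rose and 2 fell adjusted over the list alone, with Nptx2 up by 1.00 and Egr2 down by 0.92. Nefm, a neurofilament gene, fell by 1.21 among genes of axon growth and the cytoskeleton, and Ndrg1, a hypoxia-responsive gene, by 0.75 among heat shock and hypoxia genes, on the same basis. Cell cycle genes had a median of 0.00, ribosomal protein genes of -0.05 and oxidative phosphorylation genes of 0.02. The hand-picked neighbours of Sema6a on chromosome 18 had a median of 0.04, with Kcnn2 at -0.56. In these 4 lists, 0 members passed adjusted over the list alone in limma, and at an unadjusted p under 0.05 there were 1 cell cycle gene higher and 4 neighbours lower. Among sex-linked genes, Xist read 4.10 in knockout replicate 2 and 10.79 to 11.54 in the other arrays. The labels give no sex for the pooled pups.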

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

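The rules used here and the per-array tests of the microglia and GABAergic lists were chosen after the results were seen. The 3′ minus 5′ difference was singled out where 1 knockout array, and a control probe set above the median level where both knockout arrays, exceeded every control by more than the range of the controls. In the control probe sets of the array, which the comparison left out, the 3′ probe set of Gapdh exceeded the 5′ one by 2.34 on the log2 scale in knockout replicate 1, against at most 1.33 in the controls. The same difference for Actb was 1.91 in that array and at most 1.45 in the controls, and knockout replicate 2 gave 0.96 for Gapdh and 0.97 for Actb. The spiked AFFX-r2-P1-cre probe sets, the only ones where both knockout arrays met this, averaged 14.45 (3′) and 14.39 (5′) in the knockout, against highest control values of 14.43 and 14.35. The other spiked cre probe sets, named CreX, did not meet it.

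The higher level of microglia genes in both knockout pools, with a median of 1.51, was weighed against several features of the tissue. Blood in the knockout tissue would bring erythroid transcripts, whose median was -0.10 with an upper bound of 0.15. Meningeal or choroid plexus tissue would raise its own markers, whose joint median was 0.044 with an upper bound of 0.21. A loss of neurons would raise all other cell types alike. Astrocyte, oligodendrocyte and endothelial markers had a joint median of 0.13 (interval 0.09 to 0.18), a rise far smaller than 1.51. The oligodendrocyte lineage list alone had a median of 0.21 (interval 0.14 to 0.34). Neither knockout array carried the difference alone, since the smaller of the medians with 1 of them left out was 1.56. More microglia or a changed state of microglia in the knockout may underlie the pattern. This hypothesis was not itself tested, and counts of labelled microglia in sections would address it. Differences between the pools in age, litter or the share of tissue not weighed here stay open as untested. Xist was within the range of the controls in knockout replicate 1 (11.50), where the microglia median was 1.64. It was far lower in knockout replicate 2, where that median was 1.56. The Xist level does not give the share of each sex in a mixed pool, so sex composition stays open too.

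For the neuronal genes that differed, tissue from neighbouring regions was weighed. Cortical and hippocampal markers had a median of 0.12 with an upper bound of 0.40, and habenular markers a median of 0.011 with an upper bound of 0.19, both under the 0.5 set as the bound, which argues against these tissues as the source. GABAergic and prethalamic markers had a median of 1.06, which reached the value of 1 set in advance for prethalamic or other GABAergic tissue in the dissection. In knockout replicate 2 the same markers had a median of 0.09 with an upper bound of 0.20, though for 9 of 23 both knockout arrays lay above every control. Such tissue could account for differences in knockout replicate 1. The small median in replicate 2 argues against it as the source of those shared by both arrays, such as Cck and Gsg1l. Neighbouring thalamic nuclei and the genotype itself stay open for the shared differences, since the list of genes patterned between nuclei had a median of 0.00 with members that moved both ways.

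Genes near Sema6a were weighed for DNA carried along with the mutation. Within 10 Mb of the gene, 5 of 114 genes (4.39%) had an unadjusted p under 0.01, against 739 of 17917 elsewhere (4.12%), an odds ratio of 1.07 with a 95% interval of 0.34 to 2.58 (Fisher's exact test, two-sided, p = 0.812). The interval is too wide to tell a linked effect on some neighbours from none.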

How the results depend on the processing

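All alternatives here were planned. Sema6a and the genes named in each direction kept their direction under those that gave them a value. Kif26b, Evi2a, Nrgn, P2ry6, Snx31 and S100a8 had no value without probe sets under the median level. Members named from the lists were not followed gene by gene. With the mean of all probe sets of a gene, some list means shrank. That of semaphorins, plexins and neuropilins went from 0.18 to 0.02 and that of cadherins, protocadherins and contactins from 0.23 to 0.10. The mean of the axon growth list grew, from -0.08 to -0.17. Rises and falls given for members at their brightest probe set may thus not hold at others. The knockout and control titles share the numbers 1 and 2, and deviations from the group means correlated at 0.148 and 0.212, but with 2 pairs the samples share only a number. With the number as a block, 0 probe sets were higher and 0 lower at the adjusted threshold in limma, 4950 had an unadjusted p under 0.05, and Sema6a gave -2.73 (adjusted p = 0.298). Without each array in turn, 0 to 0 probe sets passed in either direction, Sema6a gave -2.73 to -2.60 (adjusted p from 0.0654 to 0.234), and the counts at an unadjusted p under 0.01 ran from 480 to 1688 higher and from 423 to 1187 lower. A single array fewer leaves 2 residual degrees of freedom, and the block leaves fewer still. Control replicate 3 is alone in its block, so the block fit takes the difference from the 2 numbered pairs only. The loss of calls under the block therefore does not show an effect of pairing. Where 1 knockout array is left, it is assumed to vary like the controls.

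Against 29 higher and 4 lower, quantile normalisation gave 7 lower, centring 7, and leaving out the dimmest 25% 8. Leaving out probe sets under the median level gave 62 higher and 36 lower, with 536 higher at an unadjusted p under 0.01. An intensity trend gave 66 and 34, array weights 16 higher, with 10 of the 14 named genes besides Sema6a still past the threshold, and an adjusted p under 0.1 gave 103 and 55. Fewer tests explain part of the gain without dim probe sets; the other causes were not tested. The number of lists called was 2, with 0 under an estimated correlation, 1 under fry, and 3 without probe sets under the median level, with the mean of all probe sets, and without knockout replicate 1, control replicate 1 or control replicate 2. The GABAergic list lost its call without knockout replicate 1 (mean 0.07, adjusted p = 0.677), and the oligodendrocyte list passed without it (0.34, adjusted p = 0.0244), without control replicate 1 (0.27, 0.0154) and without probe sets under the median level (0.30, 0.0205). The endothelial list passed without knockout replicate 1 (0.25, 0.0310) and control replicate 2 (0.25, 0.00944), and axon growth genes, on the lower side, with the mean of all probe sets (-0.17, 0.0216). Probe sets near the background are limited by signal.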

Other observations

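The gene sets of the next paragraph were chosen after their values were seen. The comparison of other groupings of the arrays was planned.

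Of 5 genes known from the amoeboid microglia of newborn white matter, picked by hand, 0 passed the adjusted threshold in limma. Igf1, a growth factor, differed by 2.42 (limma adjusted p = 0.0546), Lpl, lipoprotein lipase, by 1.98 (0.0649), and Clec7a, a glucan receptor, by 1.91 (0.123), with both knockout arrays above all controls, while Itgax differed by 0.50 and Gpnmb by 0.08. Other microglia genes outside the fixed list gave a median of 0.75 over 6 genes, from Fcrls at 1.88 and Gpr34 at 1.70 to Spi1 at 0.29 and Siglech at 0.07. Genes of border macrophages gave a median of 0.02 over 6 genes, with Lyve1 at 0.04 and Cd163 at -0.66. Of 11 neutrophil genes, whose median was -0.25, S100a8 gave -2.46 (0.0720), S100a9 -2.32 (0.0865) and Stfa3 -1.70 (0.0859), while others such as Mpo (-0.11) and Elane (0.17) lay near the floor of the array. No set test was run on these genes. In limma 0 of these genes passed the adjusted threshold, and an unadjusted p under 0.05 was reached by 4 of 5, 4 of 6, 0 of 6 and 4 of 11 genes of these sets in turn.

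Probe sets that match several genes were not named as genes. Among them, 1 for the immunoglobulin kappa family rose by 2.96, 1 for the Bcl2a1 family by 1.88 and 1 for the Ugt1a family by 1.51, all past the adjusted threshold in limma. The immunoglobulin probe set read 5.02 in the knockout and 2.05 in the control, both under the median level of 6.39. A probe set shared by the alpha protocadherin cluster on chromosome 18 gave -1.50 (adjusted p = 0.0546). The largest change of any probe set past the threshold, 3.48, was at one that is unnamed in the annotation used here.

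The 5 arrays can be split into 2 and 3 in 10 ways, of which 1, the split by genotype, gave 33 probe sets past the adjusted threshold, and the highest of the others gave 2. Splits this few cannot give a share under 0.05. The other splits mix knockout and control arrays within a group, so any genotype difference adds to their spread and lowers their counts.

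The first principal component held 47.4% of the variance and placed knockout replicate 1 at 72.6, replicate 2 at 10.4 and the controls between -32.2 and -21.5. Across probe sets, knockout replicate 2 correlated better with each control (0.990 to 0.993) than with knockout replicate 1 (0.988).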
